A study of Mus musculus with 18 samples.

How the data were processed

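RNA sequencing was described for 18 libraries from wild-type C57BL/6 mice, 6 in each of 3 groups. Per the labels' protocols, control mice received saline for 28 days, AngII mice received angiotensin II at 500 ng/kg/min, and AngII+Que mice received the same angiotensin II with quercetin at 5 mg/kg per day. The tissue label was renal. Total RNA was extracted with TRIzol, ribosomal RNA was removed with an NEBNext depletion kit and libraries were built with an NEBNext Ultra kit, per the labels' protocols. The submitters' processing notes name the mouse build mm10 and limma, with no version or model for limma. The aligner, the assembler and the annotation release are not given in the sources used here. Samples were assigned to groups from the group label. The series design gives 6 samples per group without saying how they were housed, collected or prepared together, so the p-values measure the spread between these samples.

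The deposited values are FPKM per transcript (fragments on a transcript, scaled by its length and by the library's total). This unit was not written in the files and was read from the values. In each library, low values multiplied by the transcript's length came out as whole multiples of one step for 97.5% to 100% of the 89 to 165 values checked, with a tolerance of 0.02 of a step, where chance would give 4.0%. The step gives the depth: 64100000 to 79900000 fragments per library. One fragment on a transcript of 1 kb was worth 0.0125 to 0.0156 FPKM, which is the smallest step such a transcript can show. The deposited files come in different transcript sets. The control libraries list 39458 transcripts, the AngII and AngII+Que libraries list 40152, and 36771 are common to all 18. Every transcript in the AngII and AngII+Que set has a mean of at least 0.5 FPKM in one of those groups, and every common transcript has a mean of at least 0.5 FPKM in the control or AngII group. Transcripts below such a mean were therefore not analysed here, and a gene active in 1 group alone can be missing.

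Ensembl transcripts were matched by identifier to GENCODE mouse release 21, which names 30171 of the 30205 listed. A gene's value is the sum of its transcripts common to all 18 libraries, which gave 13945 genes. Transcripts that the authors assembled themselves carry no gene name, number 10285 among the common ones and hold 6.8% to 11.5% of the summed FPKM per library. They were left out of the gene sums and tested apart. A shift of fragments between a named and an assembled transcript of one gene can therefore appear as a change of that gene, most strongly where 1 named transcript carries it. Coordinates are those of the annotation on mm10, counted from 1.

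Values were tested as log2(FPKM + 0.1), and fold changes are on that scale, which understates the change of low genes. Genes with at least 0.5 FPKM in at least 6 libraries were kept, 13785 in all. One limma fit (version 3.58.1, trend and robust, R 4.3.3) held all 18 libraries with 1 coefficient per group, and each comparison is a two-sided contrast of it. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Errors beside fold changes are standard errors, and errors beside FPKM are SDs over 6 libraries. The 48 pathway and cell type lists, 40 of them with at least 4 tested genes, were tested with camera at a preset correlation of 0.01 and adjusted together. The 3 technical lists tested were adjusted among themselves, and so were 4 lists added after the data were seen (brown adipocyte, sympathetic neuron, Schwann cell, dendritic cell and lymphoid tissue). Camera with an estimated correlation and fry were run beside them. Fry asks whether the genes of a list move one way on balance and does not set the list against other genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the values and figures.

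Groups, tests, lists and the rule for naming genes were chosen before the data were examined. The rule takes, per comparison, the 10 largest increases and 10 largest decreases among called genes with a mean of at least 1 FPKM and an established name. Directions with fewer than 5 such genes are filled to 5 with the genes of lowest p, given as not called. It adds up to 4 members of lowest p from each list discussed, and 11 fixed genes whatever their values. Of these 11, Agt, Havcr1 and Slc12a3 were not analysed here. Some genes that the rule takes are not reported here. Genes outside the rule are said to be so.

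Alternatives chosen at the same time were the replicate number as a block, median ratio scaling, limma with neither trend nor robust, no filter or a mean of at least 1 FPKM, pseudocounts of 1 and 0.01, a fit of the 2 groups compared, library weights, a fold threshold and each library left out. Alternatives added after the data were seen were transcripts in place of genes, limma-voom on fragments rebuilt from FPKM, a correction for transcript length, tissue scores as covariates, every transcript of the AngII and AngII+Que set, a fit without 4 control libraries and a fit without the 2 libraries of highest Igkc. Other groupings of the libraries were drawn 100 times of 462 possible ones per comparison. The reversal of AngII changes by quercetin was read against 100 simulated sets of unchanged groups, because both comparisons share the AngII libraries. The count of genes in both comparisons was set against such sets only after it was seen.

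The procedure was tested on simulated data with 200 changed genes among 13785. Of 50 genes changed by 1, 2, 3 and 4 log2 units, the AngII comparison with control recovered 18, 41, 40 and 46, with 5 false calls of 150. For AngII+Que against AngII these were 23, 39, 41 and 48, with 4 false calls of 155. For AngII+Que against control they were 20, 40, 41 and 46, with 14 false calls of 161. A planted list was called in the AngII comparison with control, with 0 of 40 unchanged simulated lists called by camera, while splits of the real libraries called more (medians of 5, 7 and 6 lists in the 3 comparisons). No pair of libraries held identical values.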

Results

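The data are transcript levels in 18 mouse libraries labelled renal, from 6 samples each of saline controls, mice given angiotensin II (AngII) and mice given angiotensin II with quercetin (AngII+Que). Angiotensin II is the peptide hormone of the renin-angiotensin system that constricts vessels and raises blood pressure, and quercetin is a plant flavonol. The series title concerns quercetin and the blood pressure raised by angiotensin II, and its design asks which genes differ between the groups. There was no group with quercetin alone. Depth was 64100000 to 79900000 fragments per library.

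Smooth muscle, matrix and fat cell transcripts were abundant in these libraries, and few genes of kidney tubule cells had values. Tagln and Acta2, contractile proteins of smooth muscle, ran from 1550 to 10500 and from 725 to 7570 FPKM over the 18 libraries. Mgp, a matrix protein of vessels and cartilage, ran from 3080 to 22300 FPKM. Fabp4, the fatty acid carrier of fat cells, ran from 1270 to 13100 FPKM, and Ucp1, the uncoupling protein of brown fat, from 2.08 to 5650 FPKM. These genes were chosen after their values were seen. Of the lists of tubule cell markers, the thick ascending limb had 1 of 7 genes tested, the distal convoluted tubule 1 of 5, principal cells 1 of 8, proximal tubule segments S1 and S2 1 of 8 and intercalated cells 0 of 8. Juxtaglomerular cells had 3 of 4 genes tested, pancreatic acinar cells 1 of 10 and urothelium 0 of 6, and these 8 lists were too short to test. Proximal tubule segment S3 had 4 of 8 genes tested, podocytes 6 of 10 and distal nephron transport 12 of 27. The label names no part of the kidney, and lists named for its segments are given as sets of genes, not as levels of those cells. The label was taken as given. The few tubule markers with values argue against samples made mainly of tubule cells, unless their fragments lie on assembled transcripts without a gene name. Beyond that, these values do not settle which tissue the samples hold. The lists of tubular injury, NRF2 targets, aryl hydrocarbon receptor targets, distal nephron transport, p53 targets, unfolded protein response, immediate early genes, circadian clock, nitric oxide and endothelin signalling and inflammasome genes were called in none of the 3 comparisons. Nor were those of podocytes, proximal tubule segment S3, endothelium, fibroblasts, T cells, B cells, adipocytes, hepatocytes and skeletal muscle or of replication-dependent histones (camera adjusted p from 0.0606 to 0.99 over these lists and comparisons). Among all libraries the median Spearman correlation was 0.872 within groups and 0.866 between groups. The first principal component held 14.8% of the variance, and its high end was led by Th, Npy and Dbh, genes of noradrenergic nerve cells. Its low end was led by Ccdc124, Rpl7l1 and Manbal and also held the short RNAs Rn7s1, Rn7s2, Rn7sk and Rpph1. On it 5 of 6 control libraries lay at -90.1 to -34.6 and Control replicate 5 at 22.6, the AngII libraries at -18.8 to 42.7 and the AngII+Que libraries at 0.3 to 67.1. Th was at 124 FPKM in Control replicate 5, at 83 and 54 FPKM in AngII replicates 3 and 6, and at up to 82.3 FPKM in AngII+Que.

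The comparison of AngII with control addresses angiotensin II without quercetin. Genes of the extracellular matrix stood higher with AngII and genes of oxidative phosphorylation lower, each as a list (adjusted p = 0.71 for both with an estimated correlation). The only single genes past the test were a pair of short structural RNAs. Rn7s1 and Rn7s2, copies of the 7SL RNA of the signal recognition particle, fell from 213 ± 152 and 216 ± 148 FPKM in control to 6.17 ± 5.85 and 6.15 ± 5.85 FPKM in AngII (SD, n = 6). Their log2 fold changes were -4.94 ± 0.78 and -4.99 ± 0.78 (SE, limma adjusted p = 0.041 for each), with 6 of 6 AngII libraries below the control mean. They lie on chromosome 12 of mm10 at 69159295 to 69159594 and at 69361182 to 69361481, and are near-identical copies whose fragments can be split between them. Of 13785 genes, limma called 2, with 0 higher and 2 lower, and 1557 had an unadjusted p under 0.05 where chance gives 689. Limma-voom on rebuilt fragments called 0 in this comparison, with 1533 unadjusted, and 0 in AngII+Que against AngII, with 940 unadjusted. The median of all genes was shifted by 0.137, and by 0.018 after median ratio scaling, so list medians are given relative to the median of all genes. Of 40 lists, camera called 11, with 7 higher and 4 lower, 0 of them with an estimated correlation, and fry called 2. With a correction for transcript length, chosen after the data were seen, camera called 13 lists, 10 higher and 3 lower. Of the 11 lists, 10 were still called there, so the 4 lower calls did not all hold.

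Matrix genes rose with AngII as a list, with 27 of 29 members above 0, a median 0.82 above that of all genes and camera adjusted p = 1.23e-06 (adjusted p = 0.71 with an estimated correlation). No member passed over all genes, and 2 were higher adjusted over the list alone. Ccn2, a matricellular growth factor induced by TGF-beta, averaged 370 ± 178 FPKM in control and 1440 ± 675 FPKM in AngII (log2 1.92 ± 0.53, adjusted p = 0.25). Lox, which crosslinks collagen, and Col15a1 gave log2 values of 1.02 ± 0.34 and 1.04 ± 0.39. Heat shock genes rose as a list with 14 of 16 members above 0 and 5 higher adjusted over the list alone (adjusted p = 7.68e-05, and adjusted p = 0.584 with an estimated correlation). The cytosolic chaperone Hsp90aa1 averaged 55.7 ± 16 and 125 ± 30.6 FPKM (log2 1.17 ± 0.23, adjusted p = 0.128). Hspa8, Hsph1 and Hspa1b gave 3.04 ± 0.84, 1.16 ± 0.31 and 1.41 ± 0.43. Cholesterol biosynthesis genes rose as a list (20 of 22 above 0, 1 higher adjusted over the list alone, adjusted p = 0.00296), and so did cell cycle genes (19 of 23 above 0, 5 higher adjusted over the list alone, adjusted p = 0.0051). Both lists had adjusted p = 0.71 with an estimated correlation. In the first, Cyp51, Sqle and Idi1 gave log2 values of 1.07 ± 0.23, 0.69 ± 0.25 and 0.75 ± 0.28. In the second, Top2a, Cdk1, Mcm6 and Birc5 gave 2.25 ± 0.61, 1.58 ± 0.47, 1.03 ± 0.33 and 1.78 ± 0.58. Other rises as lists were those of macrophage markers (9 of 10 above 0, adjusted p = 0.0196), of medullary osmolyte and urea handling (5 of 5, 2 higher adjusted over the list alone, adjusted p = 0.0321) and of the renin-angiotensin system (11 of 11, adjusted p = 0.0382). With an estimated correlation their adjusted p = 0.71, 0.584 and 0.71. In the osmolyte list, Slc5a3, the carrier of the osmolyte myo-inositol, gave a log2 value of 0.84 ± 0.32. Enpep, the aminopeptidase that cleaves angiotensin II, led the renin-angiotensin list at 1.38 ± 0.56. Adgre1 led the macrophage markers at 0.75 ± 0.28. Cx3cr1, also a macrophage marker, was listed at 0 in all control libraries and at 0 to 0.875 FPKM in AngII.

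Oxidative phosphorylation genes fell with AngII as a list, with 1 of 32 members above 0, a median of -0.64 relative to all genes and camera adjusted p = 1.2e-09 (adjusted p = 0.71 with an estimated correlation). Sdhb, a subunit of succinate dehydrogenase, averaged 108 ± 60.2 FPKM in control and 50.2 ± 25.8 FPKM in AngII (log2 -1.06 ± 0.38, adjusted p = 0.335). Ndufb3, Cox5b and Ndufb9 gave -0.71 ± 0.26, -0.82 ± 0.33 and -0.71 ± 0.32. Fatty acid oxidation genes fell as a list (1 of 23 above 0, adjusted p = 7.68e-05), as did the mitochondrially encoded genes (0 of 10 above 0, adjusted p = 0.00515) and neutrophil markers (1 of 6 above 0, 1 lower adjusted over the list alone, adjusted p = 0.0127), each with adjusted p = 0.71 with an estimated correlation. With tissue scores (adipocyte, smooth muscle and sympathetic neuron) as covariates, a choice made after the data were seen, the fatty acid oxidation and mitochondrially encoded calls ended, at adjusted p = 0.627 and 0.661. Angptl4, Ppargc1a and Pdk4 gave log2 values of -1.18 ± 0.44, -1.4 ± 0.74 and -1.02 ± 0.62, mt-Co2 gave -0.6 ± 0.35, and Retnlg gave -1.49 ± 0.44. Beside these lists, brown adipocyte markers fell (1 of 10 above 0, adjusted p = 0.00198, and adjusted p = 0.426 with an estimated correlation). Schwann cell markers rose (12 of 12 above 0, adjusted p = 0.000768, and adjusted p = 0.318 with an estimated correlation). Ribosomal protein genes fell as a list (11 of 83 above 0, adjusted p = 3.12e-10, and adjusted p = 0.32 with an estimated correlation). The list of nuclear-retained and other non-coding RNAs, a measure of RNA handling, fell and kept its call (1 of 5 above 0, adjusted p = 3.57e-05, and adjusted p = 0.0039 with an estimated correlation). Its members Rn7sk, the 7SK RNA that holds back transcription elongation, and Rpph1, the RNA of ribonuclease P, gave -4.51 ± 0.78 and -4.57 ± 1.01 with adjusted p = 0.0668 and 0.131.

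Of the genes named whatever their values, Ren1, Ace, Agtr1a, Lcn2, Col1a1, Col3a1, Ccl2 and Cyp1a1 did not pass in AngII against control. Col1a1 averaged 86.4 ± 67 and 146 ± 62.2 FPKM (log2 0.89 ± 0.4, adjusted p = 0.419) and Col3a1 246 ± 171 and 453 ± 225 FPKM (log2 0.98 ± 0.43, adjusted p = 0.416). Ren1, the renin gene, gave 1.01 ± 1.1, Ace 0.28 ± 0.3, Agtr1a 0.3 ± 0.64, Lcn2 0.1 ± 0.48, Ccl2 -0.21 ± 0.64 and Cyp1a1 -0.96 ± 1.14. The protein-coding genes of lowest p were Sbspon (1.39 ± 0.26, adjusted p = 0.105), the glycoprotein gene Thy1 (1.2 ± 0.24, adjusted p = 0.129), the activin antagonist Fst (2.88 ± 0.58, adjusted p = 0.129), the calcineurin regulator Rcan1 (1.02 ± 0.22, adjusted p = 0.131). On the lower side they were Commd6 (-1.47 ± 0.31, adjusted p = 0.131) and Exosc1 (-2.22 ± 0.49, adjusted p = 0.131). The call of the 2 RNAs was carried by few fits: 46 genes were called without Control replicate 5 (30 higher and 16 lower), 3 without AngII replicate 1 or 4 (each lower), and 0 by limma without any other single library, where 1075 to 1770 genes had an unadjusted p under 0.05. Leaving out the 4 control libraries of highest Rn7sk, a choice made after that value was seen, gave 11 genes, none of them these 2, and 6 lists. Limma called all 11 higher and 0 lower there, with 1231 genes at an unadjusted p under 0.05. Only Control replicates 5 and 6 were left as controls in that fit. Rn7sk went with Rn7s1 and Rn7s2 in the controls, so the choice itself worked against these 2 lower calls. In that fit cell cycle and macrophage lists reached adjusted p = 0.0637, cholesterol, osmolyte and mitochondrially encoded lists 0.153, and Schwann cell markers 0.0742. With tissue scores as covariates, the renin-angiotensin, osmolyte, macrophage and brown adipocyte lists reached 0.108, 0.084, 0.0882 and 0.85. The matrix, oxidative phosphorylation, heat shock, cell cycle, cholesterol, Schwann cell, ribosomal protein and non-coding RNA calls held without any single library. The fatty acid oxidation list reached adjusted p = 0.053 without Control replicate 3. Mitochondrially encoded genes reached 0.0911 without Control replicate 3 and 0.103 without AngII replicate 1. Neutrophil markers reached 0.053, 0.0637 and 0.0509 without Control replicates 3 and 5 and AngII replicate 2. Macrophage markers reached 0.0581, 0.107 and 0.097 without Control replicates 1 and 5 and AngII replicate 1. The osmolyte list reached 0.0561, 0.075, 0.0637 and 0.068 without Control replicates 3, 4 and 5 and AngII replicate 1. The renin-angiotensin list reached 0.0582, 0.0637, 0.0759, 0.097 and 0.132 without Control replicates 3, 5 and 6 and AngII replicates 1 and 6. Brown adipocyte markers reached 0.122 and 0.0568 without Control replicate 3 and AngII replicate 6. The number of lists was 6 without Control replicate 3 and 7 without Control replicate 5 or AngII replicate 1.

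**Figure D1:**
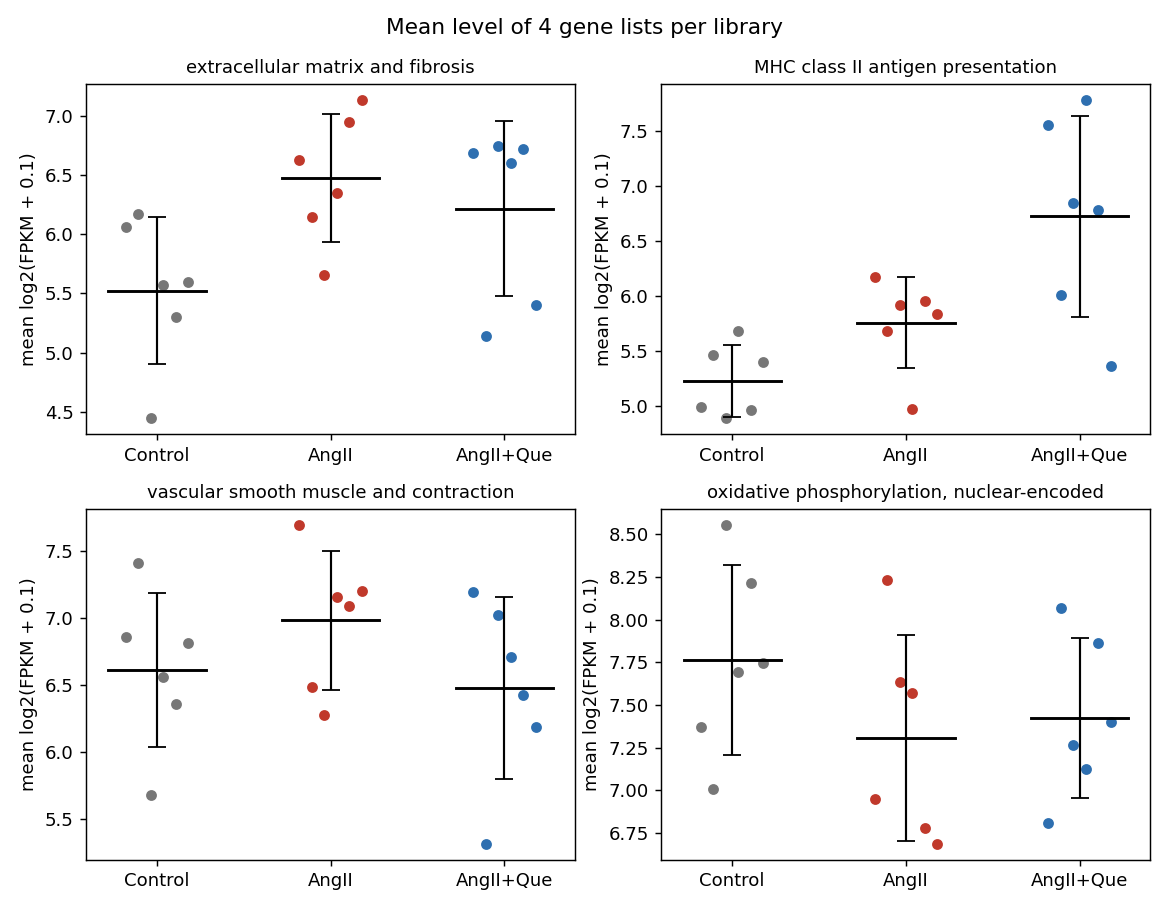
Mean log2(FPKM + 0.1) of the members of 4 gene lists in each library (points), by group, with the group mean (line) and SD (bar, n = 6). The matrix list averaged 5.52 in control and 6.47 in AngII, and the MHC class II list 5.75 in AngII and 6.72 in AngII+Que, where the spread between libraries was also wider (SD 0.92 against 0.41).

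The comparison of AngII+Que with AngII asks what quercetin changed in mice given angiotensin II. Genes of antigen presentation, interferon response and chemokines stood higher when quercetin was added, and contractile genes of smooth muscle lower, each as a list. With an estimated correlation these 4 lists had adjusted p = 0.38, 0.38, 0.38 and 0.66. Singly, 1 gene passed the test. Ncstn, which encodes nicastrin, a subunit of gamma-secretase, fell in the sum of its 2 named transcripts from 20.1 ± 3.59 FPKM in AngII to 2.72 ± 0.809 FPKM in AngII+Que (log2 -2.87 ± 0.41, limma adjusted p = 0.0213, 6 of 6 libraries below the AngII mean), with 11.5 ± 5.76 FPKM in control. It lies on chromosome 1 of mm10 at 172066013 to 172082795. Among transcripts tested singly, no Ncstn transcript was called. The 1 transcript called was an assembled one without a gene name, which went the other way, with means of 3.30 FPKM in control, 0.014 FPKM in AngII and 17.4 FPKM in AngII+Que. Fragments assigned to an assembled transcript of Ncstn in place of a named one would give the same values for the gene. Limma called 1 gene, 0 higher and 1 lower, and 1000 genes had an unadjusted p under 0.05 where chance gives 689. Of 40 lists, camera called 11, with 8 higher and 3 lower, 0 of them with an estimated correlation, and fry called 0.

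MHC class II genes rose with quercetin as a list, with 7 of 7 members above 0, 6 of them higher adjusted over the list alone and camera adjusted p = 3.44e-06 (adjusted p = 0.38 with an estimated correlation). Cd74, the invariant chain, averaged 210 ± 56.3 FPKM in AngII and 576 ± 399 FPKM in AngII+Que (log2 1.22 ± 0.37, adjusted p = 0.59), and H2-Eb1 116 ± 34.1 and 298 ± 175 FPKM (log2 1.2 ± 0.35, adjusted p = 0.545). H2-DMa and H2-Ab1 gave 1.19 ± 0.38 and 1.04 ± 0.37. The MHC class II score was highest in AngII+Que replicates 1 and 4, at 7.55 and 7.78, and was 5.36 to 6.85 in the other AngII+Que libraries. The same replicates had the highest scores of B cell (4.66 and 5.71), T cell (3.27 and 2.50) and dendritic cell markers (4.73 and 4.63), which reached 2.06, 0.48 and 1.93 in the other libraries. Without these 2 libraries, a choice made after the values were seen, the MHC class II list had camera adjusted p = 0.00105. Its score then differed by 0.49 ± 0.3 (SE), within 2 SE of 0, against 0.97 ± 0.35 with all libraries. The complement, macrophage and NADPH oxidase lists then reached adjusted p = 0.0561, 0.158 and 0.586. Interferon-stimulated genes rose as a list (24 of 26 above 0, adjusted p = 7.16e-06), as did inflammatory cytokines, chemokines and adhesion genes (16 of 20 above 0, 5 higher adjusted over the list alone, adjusted p = 0.000263), both with adjusted p = 0.38 with an estimated correlation. The chemokines Ccl8, Ccl7, Ccl5 and Ccl2 gave log2 values of 1.61 ± 0.5, 1.83 ± 0.57, 2.34 ± 0.8 and 1.84 ± 0.64, with adjusted p from 0.59 to 0.602. Usp18, Oasl2, Dhx58 and Xaf1 gave 1.11 ± 0.33, 0.8 ± 0.31, 0.88 ± 0.34 and 0.86 ± 0.36. Complement and macrophage lists rose (15 of 18 and 9 of 10 above 0, adjusted p = 0.0074 for each, and adjusted p = 0.66 for each with an estimated correlation). They were led by C3 at 1.11 ± 0.29 and Cfb at 0.68 ± 0.24, and by Cd68 at 0.76 ± 0.24. Adjusted over the list alone, 1 complement gene and no macrophage marker were higher. NADPH oxidase genes rose as a list (6 of 8 above 0, adjusted p = 0.0484, and adjusted p = 0.66 with an estimated correlation), with Rac2, Ncf4, Ncf1 and Cybb at 1.57 ± 0.63, 1.18 ± 0.54, 0.79 ± 0.37 and 0.74 ± 0.37.

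Smooth muscle genes fell with quercetin as a list, with 2 of 17 members above 0, a median of -0.72 relative to all genes and camera adjusted p = 3.19e-05 (adjusted p = 0.66 with an estimated correlation). The contractile protein genes Cnn1 and Acta2 averaged 832 ± 283 and 4680 ± 2050 FPKM in AngII and 378 ± 279 and 2470 ± 1610 FPKM in AngII+Que (log2 -1.43 ± 0.45 and -1.11 ± 0.46, adjusted p = 0.59 and 0.642). Actg2 and Kcnmb1 gave -0.86 ± 0.34 and -0.83 ± 0.35. Heat shock genes fell as a list (1 of 16 above 0, adjusted p = 0.001) and so did hemoglobin and other erythroid genes (0 of 5 above 0, adjusted p = 0.0104), both with adjusted p = 0.38 with an estimated correlation. Hsp90aa1, Hspb8, Dnajb1 and Cryab gave -0.55 ± 0.23, -0.4 ± 0.15, -0.32 ± 0.17 and -0.54 ± 0.32, and Hba-a2 and Hba-a1 gave -1.84 ± 0.8 and -0.75 ± 0.49. Fatty acid oxidation genes rose (21 of 23 above 0, 1 higher adjusted over the list alone, adjusted p = 0.0074, and adjusted p = 0.705 with an estimated correlation). So did fatty acid synthesis genes (13 of 16 above 0, adjusted p = 0.0112, and adjusted p = 0.66 with an estimated correlation). Cpt1a, the carnitine acyltransferase that admits fatty acids to mitochondria, was at 16 FPKM in AngII replicate 1, was listed at 0 in the other AngII libraries and ran from 11.3 to 21.2 FPKM in AngII+Que (adjusted p = 0.403). It rests on 1 named transcript, so fragments assigned to another transcript of the gene would give the same values. Angptl4, Fasn, Srebf1 and Pnpla3 gave 0.96 ± 0.44, 1.56 ± 0.69, 0.68 ± 0.32 and 1.71 ± 0.91. Brown adipocyte, sympathetic neuron and Schwann cell markers rose beside these lists (9 of 10, 14 of 14 and 10 of 12 above 0, adjusted p = 0.0201, 0.000976 and 0.0106, and adjusted p = 0.373, 0.373 and 0.36 with an estimated correlation). The dendritic cell list was called too (4 of 4 above 0, adjusted p = 0.0187, and adjusted p = 0.302 with an estimated correlation), but rested on AngII+Que replicates 1 and 4. Without them it reached adjusted p = 0.385. With tissue scores as covariates, fatty acid oxidation, fatty acid synthesis, brown adipocyte, Schwann cell and dendritic cell lists reached adjusted p = 0.198, 0.476, 0.656, 0.458 and 0.1. The smooth muscle and sympathetic neuron lists, whose own scores are among the covariates, reached 0.0725 and 0.656.

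Genes of lowest p that did not pass in AngII+Que against AngII were Ch25h (1.83 ± 0.41), Nbeal2 (1.19 ± 0.27), the glucose carrier Slc2a4 (1.64 ± 0.38) and the antibody gene Ighg1, listed at 0 in AngII except replicate 2, on the higher side. On the lower side they were Tnfaip3 (-3.06 ± 0.69), Coq10b (-0.89 ± 0.21), Tbc1d23 (-1.77 ± 0.42) and Usp9x (-2.84 ± 0.71). Adjusted p was 0.403 for all but Usp9x at 0.48. Of the genes named whatever their values, Ccl2 had the lowest unadjusted p in AngII+Que against AngII (adjusted p = 0.602). Cyp1a1, the textbook target of the aryl hydrocarbon receptor, gave 2.35 ± 1.14 (adjusted p = 0.697). Ren1, Ace, Agtr1a, Lcn2, Col1a1 and Col3a1 gave 1.08 ± 1.1, 0.08 ± 0.3, 0.99 ± 0.64, 0.5 ± 0.48, 0.69 ± 0.4 and 0.37 ± 0.43. The Ncstn call was lost without AngII replicates 1, 3, 5 or 6 or AngII+Que replicates 1, 2, 3, 4 or 6, where limma called 0 genes and 777 to 1240 had an unadjusted p under 0.05. The adjusted p of Ncstn reached 0.0946 without AngII replicate 6. Without AngII+Que replicates 1 and 4 together limma called 0, with 822 unadjusted. Without AngII replicate 2 or 4, 2 genes were called. The MHC class II, interferon, cytokine, smooth muscle, heat shock and erythroid calls held without any single library, and others did not. The complement list reached adjusted p = 0.0583 without AngII replicate 2 and the macrophage list 0.0575 without AngII+Que replicate 3. Fatty acid oxidation reached 0.128, 0.122, 0.416 and 0.0591 without AngII replicates 1 and 6 and AngII+Que replicates 2 and 6. Fatty acid synthesis reached 0.117, 0.0983 and 0.188 without AngII replicates 1 and 5 and AngII+Que replicate 6. The NADPH oxidase list reached 0.0542 to 0.241 in 11 of the 18 fits that left out 1 library, namely without Control replicates 1, 2, 3, 5 or 6, AngII replicates 1, 2 or 4, or AngII+Que replicates 1, 3 or 4. Schwann cell markers reached 0.119 and 0.053 without AngII replicate 5 and AngII+Que replicate 2. Brown adipocyte markers reached 0.115, 0.266 and 0.284 without AngII replicates 1 and 6 and AngII+Que replicate 2. Dendritic cell markers reached 0.068 and 0.053 without AngII+Que replicates 1 and 2, and sympathetic neuron markers 0.053 without AngII+Que replicate 2.

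The comparison of AngII+Que with control asks whether mice given both still differed from saline controls. They differed most of the 3 comparisons in number of genes: 49 genes passed, with 30 higher and 19 lower. Most of the 19 lower genes were processed pseudogenes or non-coding RNAs, and protein-coding genes were the smaller part. Antigen presentation, macrophage, complement and cell cycle genes rose as lists (adjusted p = 0.48 for each with an estimated correlation). Serpina3n, a secreted protease inhibitor of the acute phase, rose from 23.8 ± 6.52 FPKM in control to 115 ± 53.9 FPKM in AngII+Que (log2 2.19 ± 0.3, adjusted p = 0.00643), with 57.7 ± 18.1 FPKM in AngII. Thy1, named outside the rule after its values were seen, rose from 12.8 ± 2.85 to 44.2 ± 16.1 FPKM (log2 1.72 ± 0.24, adjusted p = 0.00643), and Fst from 0.989 ± 0.831 to 8.43 ± 2.33 FPKM (log2 3.46 ± 0.58, adjusted p = 0.0169). For these 3 genes, 6 of 6 AngII+Que libraries lay above the control mean. On mm10, Serpina3n lies on chromosome 12 at 104406729 to 104414329, Thy1 on chromosome 9 at 44043384 to 44048579 and Fst on chromosome 13 at 114452290 to 114458951. Unadjusted, 2209 genes had p under 0.05 where chance gives 689. The median of all genes was shifted by 0.161, and by 0.024 after median ratio scaling, under which 38 genes were higher and 50 lower. Of 40 lists, camera called 17, with 12 higher and 5 lower, 0 of them with an estimated correlation, and fry called 9.

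**Figure D2:**
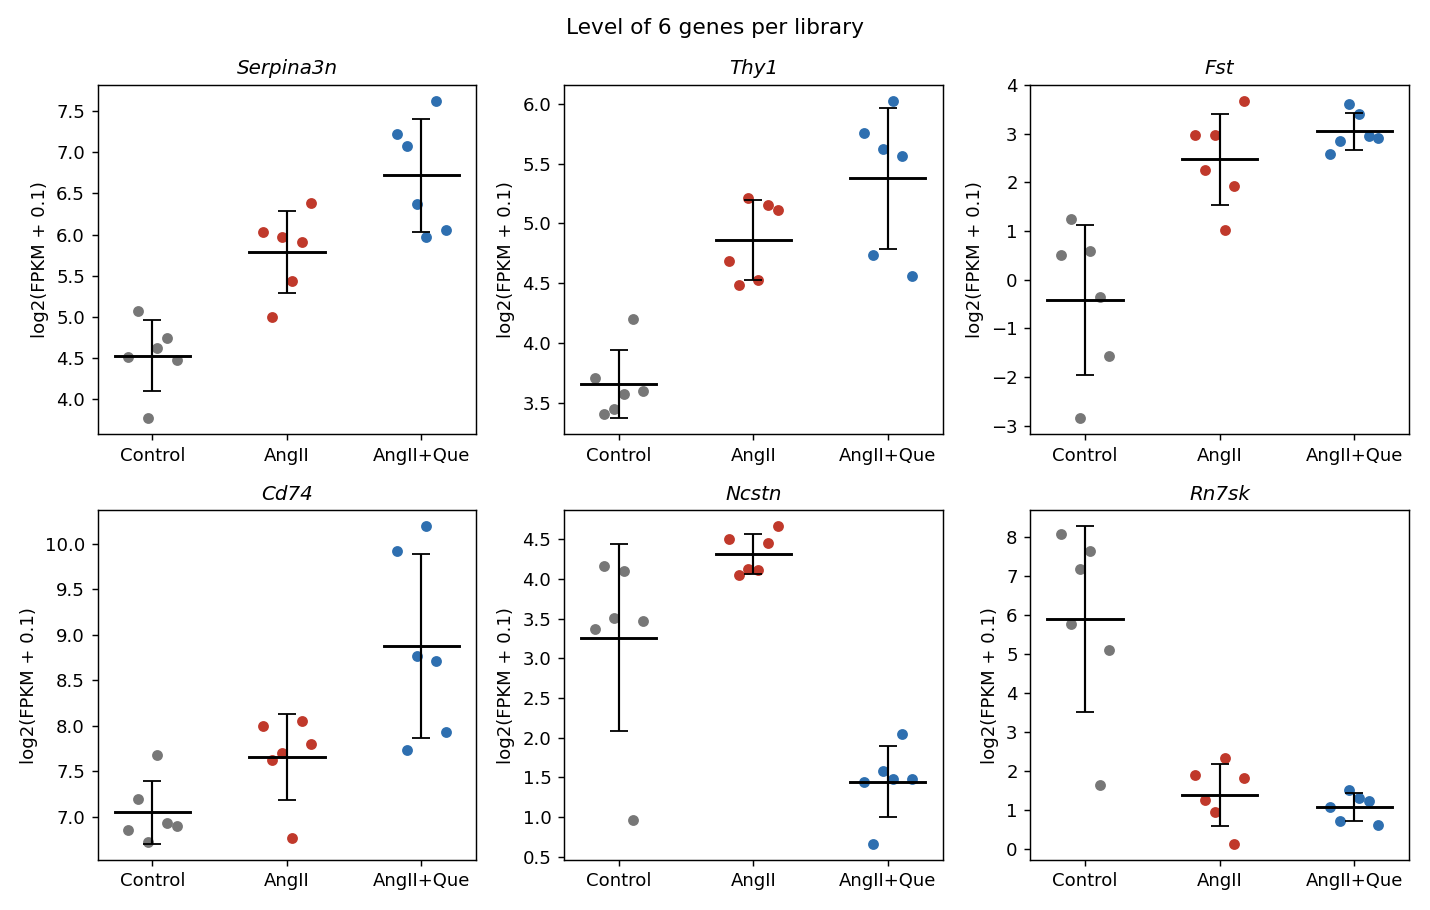
Level of 6 genes, as log2(FPKM + 0.1), in each library (points), by group, with the group mean (line) and SD (bar, n = 6). Serpina3n, Thy1 and Fst were lowest in control, Ncstn was at 2.72 ± 0.809 FPKM in AngII+Que against 20.1 ± 3.59 FPKM in AngII, and Rn7sk was above every AngII and AngII+Que library in 5 of 6 control libraries.

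Other large increases in AngII+Que over control were Ncmap and Gal3st1, which encode a myelin protein and the enzyme that makes the myelin lipid sulfatide (3.68 ± 0.74 and 2.12 ± 0.39, adjusted p = 0.0423 and 0.0265). The extracellular proteins Thbs4 and Col5a3 rose as well (3.45 ± 0.62 and 1.97 ± 0.41, adjusted p = 0.0244 and 0.0472). The actin bundler Fscn1, the cytochrome P450 gene Cyp2f2, the sphingosine 1-phosphate exporter Spns2 and the apelin receptor gene Aplnr rose by 2.12 ± 0.44, 2.1 ± 0.43, 2.02 ± 0.4 and 2.01 ± 0.39 (adjusted p from 0.0351 to 0.0475). With tissue scores as covariates 37 genes were called, 17 of them among the 49, and these 8 genes lost their call, as did Rn7sk and Rpl7l1. Schwann cell markers went the same way, with a score of 0.61 ± 0.48 in control and 2.59 ± 0.63 in AngII+Que (SD, n = 6), and so did sympathetic neuron markers, at -0.27 ± 2.79 and 2.93 ± 2.45. Both lists were added after the data were seen. Called members of the Schwann cell list are among the 49, so it gives no independent support. On the lower side, Rn7s1, Rn7s2 and Rn7sk fell (-4.82 ± 0.78, -4.83 ± 0.78 and -4.82 ± 0.78, adjusted p = 0.0149 for each), with Rn7sk at 117 ± 104 FPKM in control and 2.05 ± 0.502 FPKM in AngII+Que. Rn7sk was at 269, 54.8, 144, 199, 2.99 and 34.2 FPKM in Control replicates 1 to 6 and at 0.99 to 4.92 FPKM in the other 12 libraries. The ribosomal protein gene Rpl41 (-1.44 ± 0.25, adjusted p = 0.0178), the translation initiation factor subunit Eif3i (-1.66 ± 0.28, adjusted p = 0.0169), Commd6 (-1.76 ± 0.31, adjusted p = 0.0208) and Lamtor2, a part of the Ragulator complex on lysosomes (-0.95 ± 0.17, adjusted p = 0.0247), also fell. Rpl7l1 passed as well (adjusted p = 0.0279), at 23.7 ± 9.87 FPKM in control, and was listed at 0 in AngII+Que except in replicate 3 at 0.00502 FPKM. It rests on 1 named transcript, so fragments assigned to another transcript of the gene would give the same values.

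MHC class II genes rose in AngII+Que over control as a list, with 7 of 7 above 0, 2 called over all genes and 7 higher adjusted over the list alone (camera adjusted p = 2.42e-07, and adjusted p = 0.48 with an estimated correlation). The called members were Cd74 (1.83 ± 0.37, adjusted p = 0.0423) and H2-Eb1 (1.7 ± 0.35, adjusted p = 0.0428), beside H2-Aa and H2-Ab1 at 1.57 ± 0.37 and 1.52 ± 0.37. Macrophage markers rose (10 of 10 above 0, 1 called, 6 higher adjusted over the list alone, adjusted p = 2.59e-05), with the lysosomal protein gene Cd68 called (1.31 ± 0.24, adjusted p = 0.0279) and Csf1r and Adgre1 at 1 ± 0.26 and 1.03 ± 0.28. Cd74, H2-Eb1 and Cd68 lost their call with tissue scores as covariates and without AngII+Que replicates 1 and 4, the libraries of highest B cell and T cell scores. Complement genes rose (17 of 18 above 0, 9 higher adjusted over the list alone, adjusted p = 3.83e-05), with C6, C3ar1, Cfb and C3 at 2.77 ± 0.62, 1.05 ± 0.28, 0.9 ± 0.24 and 1.03 ± 0.29. Cell cycle genes (19 of 23 above 0, 11 higher adjusted over the list alone, adjusted p = 0.000151), interferon-stimulated genes (23 of 26, 9 of them, adjusted p = 0.000613) and cytokines and chemokines (17 of 20, 10 of them, adjusted p = 0.00133) rose as lists. With an estimated correlation the macrophage, complement, cell cycle, interferon and cytokine lists each had adjusted p = 0.48. Among their members, Top2a and Birc5 gave 2.54 ± 0.61 and 2.32 ± 0.58, Usp18 and Rsad2 gave 1.17 ± 0.33 and 3.39 ± 0.99, and the chemokine gene Cxcl10 gave 3.81 ± 0.93, none of them past the test over all genes.

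Matrix genes rose in AngII+Que over control as a list (26 of 29 above 0, 7 higher adjusted over the list alone, adjusted p = 0.00453, and adjusted p = 0.638 with an estimated correlation). Col1a1 was at 230 ± 85.7 FPKM (log2 1.58 ± 0.4, adjusted p = 0.0795) and Col3a1, Tgfb1 and Lox at 1.35 ± 0.43, 0.84 ± 0.24 and 1.04 ± 0.34. Fatty acid synthesis (14 of 16, 3 higher adjusted over the list alone, adjusted p = 0.01), cholesterol biosynthesis (18 of 22, adjusted p = 0.0117) and NADPH oxidase genes (7 of 8, 5 higher adjusted over the list alone, adjusted p = 0.0128) rose, with adjusted p = 0.592, 0.6 and 0.531 with an estimated correlation. Scd2, Cyp51 and Cybb led them by p or size at 1.39 ± 0.34, 0.77 ± 0.23 and 1.43 ± 0.37. Proximal tubule transport genes rose as a list (6 of 6 tested of 26, 1 higher adjusted over the list alone, adjusted p = 0.0384) and so did adrenal markers (4 of 4, adjusted p = 0.0465), with adjusted p = 0.48 and 0.531 with an estimated correlation. The tested transport genes included Slc7a8 and Aqp1, which other tissues also express (1.47 ± 0.37 and 0.53 ± 0.21). The adrenal list held Dbh, Th, Star and Chga, of which Dbh and Th also mark sympathetic nerve cells (4.35 ± 1.86 and 4.98 ± 2.2). Oxidative phosphorylation genes fell (4 of 32 above 0, adjusted p = 3.9e-06, and adjusted p = 0.592 with an estimated correlation), as did neutrophil markers (1 of 6, 2 lower adjusted over the list alone, adjusted p = 0.000617, and adjusted p = 0.48 with an estimated correlation). Sdhb and Atp5j gave -1.08 ± 0.38 and -0.49 ± 0.18, and Retnlg and S100a9 gave -2.04 ± 0.44 and -2.98 ± 0.99. Mitochondrially encoded (0 of 10 above 0, adjusted p = 0.0351), smooth muscle (6 of 17, adjusted p = 0.0384) and erythroid genes (1 of 5, adjusted p = 0.0496) fell as lists near the threshold, with adjusted p = 0.638, 0.734 and 0.48 with an estimated correlation. After median ratio scaling the mitochondrial and erythroid lists had adjusted p = 0.0917 and 0.12. Schwann cell markers rose beside all of these (12 of 12 above 0, 2 called, 9 higher adjusted over the list alone, adjusted p = 1.25e-06, and adjusted p = 0.0836 with an estimated correlation), as did sympathetic neuron markers (13 of 14, adjusted p = 0.000802, and adjusted p = 0.396 with an estimated correlation). Ribosomal protein genes fell (16 of 83 above 0, 1 called, adjusted p = 4.71e-09, and adjusted p = 0.364 with an estimated correlation). The non-coding RNA list fell (2 of 5, adjusted p = 0.0384, and adjusted p = 0.165 with an estimated correlation), with Meg3 at 2.61 ± 0.76 against the fall of Rn7sk.

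Ren1, Ace, Agtr1a, Lcn2, Ccl2 and Cyp1a1 gave 2.09 ± 1.1, 0.36 ± 0.3, 1.29 ± 0.64, 0.6 ± 0.48, 1.63 ± 0.64 and 1.4 ± 1.14 in AngII+Que against control, and none passed. Serpina3n, Thy1, Fst, Rn7sk, Rn7s1 and Rn7s2 kept their call in all 18 fits that left out 1 library. Cd74, H2-Eb1 and Cd68 kept it in 6, 5 and 10 of 18, with their highest adjusted p at 0.101 and 0.112 without AngII+Que replicate 1 and 0.0842 without Control replicate 1. The number of genes was 9 without Control replicate 1, 26 without Control replicate 3, 30 without Control replicate 4, 196 without Control replicate 5 and 20 without Control replicate 6. It was 30 without AngII replicate 5, and 26, 352, 30, 16, 26 and 150 without AngII+Que replicates 1 to 6. Limma-voom on rebuilt fragments called 2 genes, Serpina3n and Thy1. The fit without the 4 control libraries of highest Rn7sk called 16 genes, of which Fst alone was among the 49, and 10 lists. Limma called all 16 higher and 0 lower there, with 1270 genes at an unadjusted p under 0.05, so each of the 19 lower calls ended. Control replicates 5 and 6 were the only controls left in that fit. In it the cytokine, NADPH oxidase, proximal tubule transport, mitochondrial and cholesterol lists reached adjusted p = 0.0927, 0.23, 0.396, 0.294 and 0.177. Fatty acid synthesis, smooth muscle, adrenal, non-coding RNA and sympathetic neuron lists reached 0.0624, 0.274, 0.437, 0.399 and 0.558. With tissue scores as covariates, proximal tubule transport, cholesterol, adrenal, non-coding RNA and sympathetic neuron lists reached 0.101, 0.608, 0.613, 0.0895 and 0.928. The sympathetic neuron score is among the covariates, and Dbh and Th of the adrenal list also mark sympathetic nerve cells. The loss of those calls therefore decides nothing. Without AngII+Que replicates 1 and 4 together 10 genes were called, all of them among the 49, with Serpina3n and Thy1 the higher ones. NADPH oxidase, oxidative phosphorylation, mitochondrial, erythroid and non-coding RNA lists then reached adjusted p = 0.14, 0.0733, 0.607, 0.0642 and 0.104. Of the lists, the MHC class II, macrophage, complement, cell cycle, interferon, cytokine, matrix, NADPH oxidase, oxidative phosphorylation, neutrophil, Schwann cell and ribosomal protein calls held without any single library. Cholesterol biosynthesis reached adjusted p = 0.0509, 0.0527, 0.113 and 0.0914 without Control replicates 2 and 6 and AngII+Que replicates 2 and 6. Fatty acid synthesis reached 0.117 and 0.0727 without Control replicate 2 and AngII+Que replicate 6, and sympathetic neuron markers 0.08 without AngII+Que replicate 2. Proximal tubule transport reached 0.0768 to 0.175 without Control replicates 1, 2 or 4 or AngII+Que replicates 2 or 6. Smooth muscle reached 0.0616 to 0.272 without Control replicates 1, 2 or 6 or AngII+Que replicates 2 or 6. The non-coding RNA list reached 0.0556 to 0.0858 without Control replicates 1, 3 or 4 or AngII+Que replicates 1 or 5. The mitochondrial list reached 0.0593 to 0.306 without Control replicates 1, 3, 4 or 5 or AngII+Que replicates 1, 3 or 4. Adrenal markers reached 0.0505 to 0.194 without Control replicates 1, 2, 3, 4 or 6, AngII replicate 1 or AngII+Que replicates 2, 3, 4 or 6. Erythroid genes reached 0.052 to 0.189 without Control replicates 1, 3, 4, 5 or 6, AngII replicates 3 or 5 or AngII+Que replicates 2 to 6.

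Whether quercetin reversed what AngII had changed was asked across all 13785 genes. No gene was called in both AngII against control and AngII+Que against AngII, so the 2 RNAs lower with AngII and Ncstn lower with quercetin are separate genes. With unadjusted p under 0.05 in both, 184 genes remained, 162 of them in opposite directions (63 lower then higher, 99 higher then lower) and 22 in the same direction. The shared AngII libraries give opposite directions by themselves: in 100 simulated sets of unchanged groups, 13 to 1132 genes met this bound (mean 132), and on average 98.9% of them went in opposite directions, against 88.0% here. At least 162 opposite genes came up in 21 of the 100 sets. The log2 fold changes of the 2 comparisons correlated across genes with r = -0.294 and rho = -0.287, where genes are not independent replicates. Both comparisons share the AngII libraries with opposite sign, and simulated unchanged groups gave a mean r of -0.483, between -0.715 and -0.065. With the AngII libraries split 3 and 3 between the comparisons, r averaged 0.053 over 20 arrangements, between -0.032 and 0.184, against 0.005 for simulated unchanged groups (between -0.458 and 0.411). The covariance was -0.116 against -0.156 simulated, a difference of 0.04. The negative correlation was therefore no stronger than shared libraries alone gave. In a simulated full reversal the split correlation was -0.895, but there every gene was changed, with an SD of 2 log2 units. That value does not show whether a smaller reversal would have been seen.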

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

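The tests of explanations for the short RNAs and for the MHC class II and smooth muscle genes were chosen only after the results were seen.

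Libraries far from the other 5 of their group were looked for in 169 named genes, in the list scores and in library measures such as depth, over 662 groups of 6 libraries in all. The value in brackets is the gap of the highest or lowest library to its nearest neighbour as a share of the group's range on the log2 scale, and values past the critical value of Dixon's test are given. There were 55 such cases, and chance gives about 1 in 20 groups, here 33. Control replicate 1 lay far above its group in Commd6 (0.634) and far below its group in Slc22a18 (0.699), Mvd (0.733) and the score of endothelium (0.732). Control replicate 2 lay far above its group in Ren1 (0.634) and far below its group in Cpt1b (0.799), Ccr7 (0.648) and the score of T cell (0.729). Control replicate 3 lay far below its group in Ace (0.741). Control replicate 4 lay far above its group in Cd68 (0.671) and far below its group in Nfat5 (0.696). Control replicate 5 lay far above its group in Cdh19 (0.742), Dbh (0.708), Syt1 (1), Slc7a8 (0.759), Th (0.787), Tubb3 (0.784), the score of adrenal (0.668) and the score of sympathetic neuron (0.721) and far below its group in Rn7s2 (0.708), Rn7s1 (0.655) and Ncstn (0.753).

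AngII replicate 1 lay far above its group in Rpl36 (0.665), Cpt1a (1), C1qa (0.713) and Myl9 (0.682). AngII replicate 2 lay far above its group in Ighg1 (1) and far below its group in Ppargc1a (0.64) and Nfat5 (0.682). AngII replicate 4 lay far below its group in Dhx58 (0.63), Cd74 (0.663), Cxcl10 (0.747) and H2-Aa (0.637). AngII replicate 5 lay far below its group in Pnpla3 (0.626), Slc22a18 (0.632) and Rsad2 (0.753). AngII replicate 6 lay far below its group in Il34 (0.634).

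AngII+Que replicate 1 lay far below its group in Aplnr (0.635). AngII+Que replicate 2 lay far above its group in mt-Co2 (0.635) and mt-Cytb (0.669) and far below its group in Ace (0.817), Des (0.65), the score of nitric oxide, endothelin and natriuretic peptide signalling (0.728) and the score of erythroid (0.694). AngII+Que replicate 3 lay far above its group in the score of medullary osmolyte and urea handling (0.649). Its Rpl7l1 value (1) was flagged only because the rest of the group was tied. The log2 levels there were -3.25 against -3.32, both near the floor of the scale. AngII+Que replicate 5 lay far above its group in the score of skeletal muscle (0.79) and far below its group in S100a9 (0.759) and Th (0.71). AngII+Que replicate 6 lay far above its group in Fasn (0.718) and the score of fatty acid synthesis (0.827) and far below its group in Cdk1 (0.765), Hspa8 (0.646), Coq10b (0.646) and Rpl35a (0.631).

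Assembled transcripts without a gene name, which enter no gene value above, were tested apart, 9314 of 34588 transcripts. Of these, 2 were called higher in AngII than in control, 1 in AngII+Que than in AngII and 12 in AngII+Que than in control, where 7 were called lower.

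Rn7s1, Rn7s2 and Rn7sk were lower in the AngII and AngII+Que libraries than in 5 of 6 control libraries. A length trend shared by most genes is argued against as the whole cause. After a correction for it, the mean log2 fold change of the 3 genes in AngII against control was -4.79 ± 0.82 (SE), and -4.81 ± 0.82 before. The correction follows the bulk of genes, so it cannot test an effect limited to very short RNAs, which stays open. The calls of Rn7s1 and Rn7s2, at adjusted p = 0.041 before, ended with the correction, and why the p rose was not tested. Within the 6 control libraries, Rn7sk went with the mean of Rn7s1 and Rn7s2 (r = 0.99, exact permutation p = 0.00139, rho = 1, exact permutation p = 0.00278), and without the 2 libraries farthest from the median r was 0.99, which decides nothing, since any shared cause would give it. A difference between library preparations and a response to angiotensin II both stay open, as untested: preparation and group cannot be told apart, since the libraries that hold much of these RNAs are all controls.

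MHC class II genes were higher and smooth muscle genes lower in AngII+Que than in AngII. Varying pieces of fat and nerve in the samples stay open for the MHC class II list. With tissue scores as covariates its camera adjusted p was 7.21e-07, and 3.44e-06 before, so the covariates did not remove the call. This decides little, since camera at the preset correlation called a median of 7 lists in other splits of these libraries. With an estimated correlation the list was not called before the covariates. For the smooth muscle list the covariates decide nothing, since a smooth muscle score is among them. A lower share of smooth muscle stays open: the MHC class II score rose by 0.97 ± 0.35 (SE), and by 0.68 ± 0.44 over the mean of the endothelium, fibroblast and adipocyte scores, which is within 2 SE of 0. Lymphoid tissue in AngII+Que replicates 1 and 4, which held the most Igkc and the highest MHC class II, B cell and T cell scores, stays open: without them the MHC class II score differed by 0.49 ± 0.3 (SE), within 2 SE of 0, while the list's camera adjusted p was 0.00105. A response of MHC class II genes to quercetin stays open too, as an untested hypothesis.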

How the results depend on the processing

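The fits without 4 control libraries, without the 2 libraries of highest Igkc, on transcripts, with limma-voom, with the length correction, with tissue scores and with every transcript of the AngII and AngII+Que set, and the lists without 1 library, were chosen after the results were seen. In AngII against control, limma called 2 genes. It called 0 without trend and robust (1523 at an unadjusted p under 0.05), 0 in a fit of the 2 groups compared (1503), 0 with library weights (1612) and 0 with the length correction (1427), limma-voom called 0 (1533), transcripts gave 6, and the fit without the 4 controls of highest Rn7sk gave 11, all higher. In AngII+Que against AngII, 1 gene was called, 3 with library weights, 2 with every transcript of the AngII and AngII+Que set, 0 by limma-voom (940), 0 by limma with tissue scores (1444) and 0 by limma without the 2 libraries of highest Igkc (822). In AngII+Que against control, 49 were called, 88 with median ratio scaling, 91 without trend and robust, 76 with a pseudocount of 1, 13 in a fit of the 2 groups compared, where fewer samples set the spread, 469 with library weights, 2 by limma-voom, 16 without the 4 controls, all higher, 10 without the 2 libraries of highest Igkc and 37 with tissue scores, 17 of them among the 49. Lists called in AngII against control numbered 11, and 6 with tissue scores, 6 without the 4 controls, 0 by camera with an estimated correlation and 2 by fry. With the length correction they numbered 13, with 10 higher and 3 lower, where the main test had 4 lower. In AngII+Que against AngII they numbered 11, and 0 by camera with an estimated correlation and 0 by fry. In AngII+Que against control they numbered 17, and 10 without the 4 controls, 0 by camera with an estimated correlation and 9 by fry. The causes of these differences between settings were not tested. Leaving out 1 library gave 0 to 46, 0 to 2 and 9 to 352 genes in the 3 comparisons, and 6 to 15, 8 to 14 and 12 to 17 lists. The correlation of the AngII and quercetin changes, -0.294, ran from -0.388 to -0.202 without 1 library and turned to 0.053 with the AngII libraries split, which removes the libraries both comparisons share. The first principal component held 14.8% of the variance, and 22.4% over the 500 most variable genes. Of 7976 values of the genes taken by the naming rule under other settings, 7610 stayed on the same side of the threshold, 274 lost it and 92 gained it. Direction was compared only where the main fit or the other setting called the gene, and there 0 reversed. Of 1347 values of lists called in the main test, 1105 kept their call and direction and 242 lost the threshold.

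With the replicate number as a block, AngII+Que against AngII had 0 genes by limma (838 unadjusted) and AngII+Que against control 16, and smooth muscle and adrenal lists in the latter had adjusted p = 0.0538 and 0.0691. The numbers pair no samples: 0 of 18 same-number pairs correlated above 0.1 (median -0.04), and 0 libraries correlated best with their own number.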

Other observations

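The tests with the adipocyte score and the regroupings of the 18 libraries for the reversal were chosen only after the results were seen.

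Some transcripts were far higher in some libraries than in the rest. Igkc, the kappa light chain of antibodies, was at 1680 and 2000 FPKM in AngII+Que replicates 1 and 4 and at up to 46.7 FPKM in the other libraries, and the same replicates had the highest MHC class II scores. Ckm, the creatine kinase of skeletal muscle, was at 240 FPKM in AngII replicate 4 and 422 FPKM in AngII+Que replicate 5, and at up to 31.6 FPKM elsewhere. Npy, a neuropeptide of sympathetic nerve cells, was at 387 FPKM in Control replicate 5, at 206 and 173 FPKM in AngII replicates 3 and 6, at 36.5, 350, 71.6, 155 and 265 FPKM in AngII+Que replicates 1, 2, 3, 4 and 6, and at up to 19.4 FPKM elsewhere. Adipoq, a hormone of fat cells, was at 0.109 FPKM in AngII replicate 6 and at 91.5 to 873 FPKM elsewhere. Other fat cell genes were mixed in that library. Fabp4 and Cfd, at 2000 and 1580 FPKM, lay within the range of the other libraries, and Ucp1 was lowest of all there, at 2.08 FPKM. These genes were chosen after their values were seen.

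Matrix genes were higher and fatty acid oxidation genes lower in AngII than in control. With the adipocyte score as covariate the mean log2 fold change of the matrix genes over all genes was 0.6 ± 0.21 (SE), and 0.8 ± 0.33 before. This argues against less fat as the whole cause only as far as the score follows fat. The score is a mean of a few markers and can miss part of it, so less fat is not excluded. For the fatty acid oxidation genes the mean was -0.41 ± 0.29 with the covariate and -0.75 ± 0.51 before. Both were within 2 SE of 0, so less fat stays open there. A response of matrix genes to angiotensin II is a candidate explanation, as a hypothesis.

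Other splits of the 12 libraries compared were drawn, 100 per comparison with the real one included. In AngII against control, 6 of 100 gave at least the 2 genes of the real split, and 11 of 100 at least its 11 lists, so chance is not excluded for either. The highest other split called 567 genes and the next highest 30. What the split with 567 genes separates was not tested. The highest number of lists in another split was 15. In AngII+Que against AngII, 11 of 100 gave at least 1 gene (highest other 2) and 25 of 100 at least 11 lists (highest other 19), so chance is not excluded. In AngII+Que against control, 2 of 100 gave at least 49 genes (highest other 121) and 3 of 100 at least 17 lists (highest other 19), each a share under 0.05. These shares were not adjusted over the comparisons. A low share also does not separate treatment from library preparation, which cannot be told apart from group here. The median number of lists over the other splits was 5, 7 and 6 in the 3 comparisons. For the reversal, 99 of 100 regroupings of the 18 libraries gave a correlation as negative as -0.294, with a median of -0.502 over the others and the most negative at -0.705. Chance is not excluded, and the real value was less negative than most regroupings, which is the side away from a reversal.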
